A study of Arabidopsis thaliana with 20 samples.

How the data were processed

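Whole 10-day-old seedlings of the Arabidopsis thaliana line L119, which the labels give as wild type in the Columbia background, and of the mutant rtel1-3 were profiled by bisulfite sequencing, ChIP-seq and RNA-seq. Per the labels, each genotype had 1 bisulfite library, 1 ChIP library for each of H3, H3K9me2, H3K27me3 and H3K4me3, 1 input library, 2 RNA libraries from untreated seedlings and 2 from seedlings germinated on 1 mg/L zebularine. Nothing in the labels says whether the paired RNA libraries came from separate plants or cultures. Sequencing was on a HiSeq 2000, with single-end 50-bp reads for ChIP-seq, per the labels' protocols. The submitters' processing notes name Bowtie2, TopHat, Cufflinks and Bismark and the genome build TAIR10, without versions or settings.

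For bisulfite sequencing the authors deposited, per cytosine of the 5 nuclear chromosomes and separately for each strand and sequence context (CG, CHG and CHH, where H is A, C or T), counts of methylated reads and of all reads. A percent methylation stands beside them in the deposited files and equals the methylated count over the total count in every line. Cytosines without a read are not listed, and no filter or conversion rate is given in the sources used here. For ChIP-seq the authors deposited 1 peak list per antibody and genotype, with a score per peak of the kind the caller MACS writes and, per the file names, the input of the same genotype as control. Those scores were used only to rank or filter peaks within a list, except where median scores are given and where a common score minimum was applied to both lists as an alternative. Peaks were called per library, and the caller's version and settings are not given in the sources used here.

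For RNA-seq the authors deposited 4 lists of called genes, up and down in rtel1-3, without and with zebularine, each with a fold change and a p-value. The fold changes were read as log2 values: per the file headers they are a modified fold change, they are signed, their absolute values start at 1, and in the 4 deposited lists between 14% and 15.8% of the values (92, 49, 69 and 37 genes) lie under 1.1 in size, which on a linear scale would be almost no change. The base is an inference from these values, since no source used here states it. Whether the deposited p-values are adjusted is not stated, and the highest in any list is 0.00497. Titles of the untreated lists name L119 as the comparison group, whereas the titles of the zebularine lists name none. The p-values of the untreated lists are continuous and those of the zebularine lists all lie on steps of 5e-05, so the 2 pairs of lists were made differently. No values per replicate, expression levels or uncalled genes were analysed here, so a count of members adjusted over the list alone could not be computed for any gene list, replicates could not be left out, and an expression filter or another q-value threshold was not run.

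Gene names, biotypes and positions came from NCBI's gene table for TAIR10.1, whose coordinates are not printed. It matched 556 of 588 and 319 of 350 identifiers in the untreated up and down lists, and 477 of 477 and 233 of 234 in the zebularine lists. That the calls share its coordinates was checked on tRNA genes: conserved bases at fixed distances from the end of the gene, read from covered cytosines of either strand, were in place for 563 of 625 genes unshifted and for at most 63 at each of 24 shifts. This table has no strand and no transposable element features. Flanks were therefore taken on both sides of a gene in place of its upstream side, and annotated pseudogenes (which hold every called gene described as a transposable element that has a gene identifier), gene-poor windows and bins with CHG methylation of at least 20% stood in for transposons. For peaks these bins were chosen by their level in L119, and for methylation levels by the mean of both libraries.

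Methylation levels are methylated over all read calls, pooled over the cytosines of a region. Gene-poor windows are 100-kb windows of which protein-coding genes cover under 25% (186 of 1193). Differentially methylated bins were 200-bp bins with at least 4 cytosines of at least 4 reads in both libraries, a difference of at least 40 (CG), 20 (CHG) or 10 (CHH) percentage points, and a two-sided Fisher's exact test on reads with a Benjamini-Hochberg adjusted p under 0.01. Applying the rule to the 2 strands of 1 library gave the noise within a library, which says nothing of differences between plants. Peaks were called shared when they overlapped a peak of the other genotype by at least 1 bp. Called genes were tested with two-sided Fisher's exact tests against the 17754 of 27444 nuclear protein-coding genes with an H3K4me3 peak in either genotype, and mean methylation of called genes with permutation tests of 100000 resamples, for which 1e-05 is the smallest p. The Benjamini-Hochberg adjustment ran over all tests of a family. Because there is 1 bisulfite and 1 ChIP library per genotype, tests on reads or peaks compare libraries or lists and not genotypes, and genes, peaks and reads are not replicates. Confidence intervals are exact binomial (Clopper-Pearson) at 95% and cover counting error only.

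The scripts were tested on simulated data. Of 200 bins changed by 60 (CG), 30 (CHG) or 15 (CHH) points among the real bins, 97.5%, 62.5% and 74.5% were recovered and 0 unchanged bins were called. All 200 of 200 true partners among 3000 simulated peaks were found under each overlap rule. The permutation and Fisher tests recovered 40 of 40 simulated effects each and called 0 and 1 of 160 null cases. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1 were used.

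The groups, the tests, 11 gene lists, the thresholds, most alternatives and the rule for naming genes were fixed before the data were examined. The rule names RTEL1, up to 4 called members per list and direction (more where a list is described in full), the 5 genes with the smallest p per list (ties by size, since no expression level was used), each chromosome, a set of known silenced loci, 3 called bins per context and direction with at least 10 reads per cytosine, and the 3 peaks with the highest score per mark and genotype found in that genotype alone. Genes named outside this rule are said to be chosen after their values were seen. Peaks tied in score were taken in order of position. Alternatives covered coverage minima, per-cytosine means, strands, chromosomes left out, bin sizes and thresholds, peak score minima, merging and overlap rules, definitions of heterochromatin, fold-change thresholds, gene backgrounds and flank sizes.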

Results

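Seedlings of the mutant rtel1-3 were compared with those of L119, the line labelled wild type, to ask how DNA methylation, histone H3 and its modifications, and transcript levels differ when RTEL1 is mutated. RTEL1 (AT1G79950) is a DNA helicase that acts in DNA repair and telomere maintenance. All seedlings were 10 days old. Zebularine, given at 1 mg/L to part of the RNA samples, is a cytidine analogue that traps DNA methyltransferases on DNA. The bisulfite calls comprised 534476561 read calls over 41606972 cytosines in L119 and 442433093 over 41542234 in rtel1-3. Mean coverage of covered cytosines was 13.97 to 13.98 per strand in CG, 13.93 to 13.99 in CHG and 12.4 to 12.5 in CHH in L119, against 11.2, 11.2 to 11.3 and 10.4 to 10.5 in rtel1-3. Depths of the ChIP and RNA libraries were unknown. Each genotype had 1 bisulfite and 1 ChIP library per antibody, so differences in methylation and in peaks have no replicate check and describe these libraries.

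The RTEL1 gene itself differed in methylation between the lines. Its body had less CG methylation in rtel1-3, 28.9% (27.5 to 30.5, 3548 reads) against 45.4% in L119 (95% interval 43.9 to 46.8, 4560 reads), and carried CHG methylation of 17.2% (16.2 to 18.3, 5337 reads) in rtel1-3 against 0.406% (0.270 to 0.586, 6894 reads) in L119. CHH methylation of the body was 0.301% and 3.09%. The CHG methylation lay in the 4800 bp from 30075201 to 30080000 on chromosome 1 (TAIR10), where it reached 27.3% (25.8 to 28.8) against 0.484% (0.307 to 0.725). On the 2 strands of this part it was 26.99% and 27.62%. Of 26218 gene bodies with enough reads, 17 including RTEL1 gained as much CHG methylation, and of the 5940 with CG but little CHG methylation in L119, RTEL1 was the 1. Within the gene, the 100 bp from 30075501 to 30075600, the bin with the lowest relative depth, had 1.17 reads per cytosine in rtel1-3 against 9.74 in L119. RTEL1 carried an H3K4me3 peak in both genotypes and no peak of H3, H3K9me2 or H3K27me3 in either. It was in none of the authors' 4 lists of called genes, which give no level for a gene that was not called, so transcript levels do not check the genotype labels here.

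**Figure D1:**
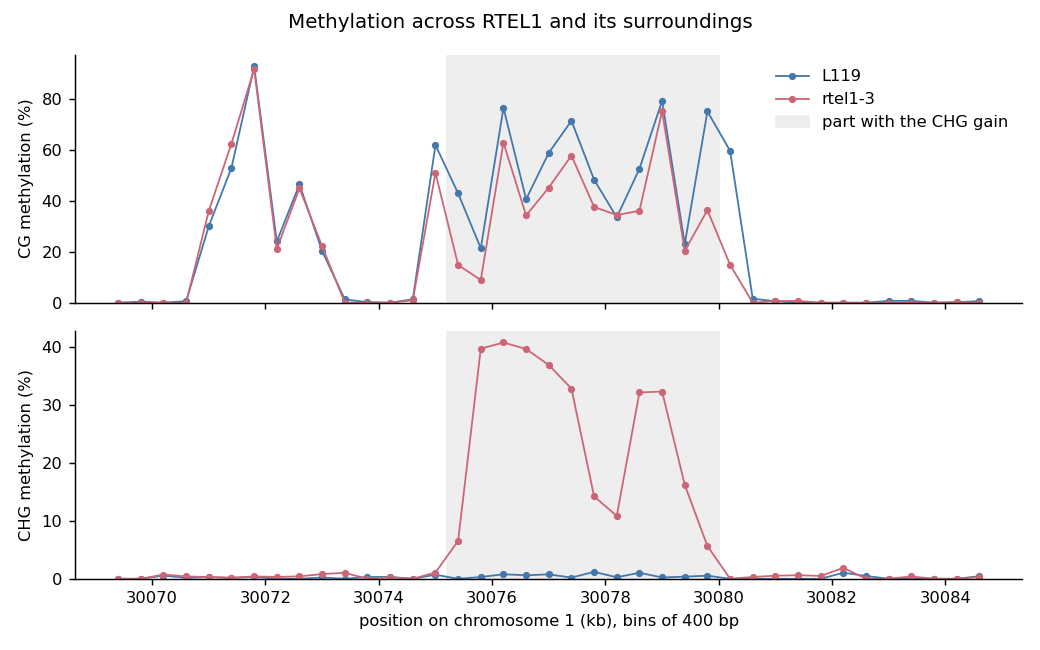
CG methylation (upper panel, percent) and CHG methylation (lower panel, percent) in 400-bp bins across RTEL1 and its surroundings on chromosome 1 (position in kb), 1 line per library. In the shaded 4800 bp, CHG methylation was 0.484% in L119 and 27.3% in rtel1-3, while CG methylation was 56.4% and 42.8%.

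Heterochromatic sequence carried more CHG methylation in the rtel1-3 library. In gene-poor windows, which hold the pericentromeres, CHG methylation was 36.9% in L119 and 40.3% in rtel1-3, and 184 of 186 such windows were higher, with a median difference of 3.43 percentage points (SD 1.44). With coverage of at least 10 the pooled difference was 1.68 points in place of 3.42, and 1.14 in place of 3.04 in pseudogenes. Annotated pseudogenes had 43.0% in L119 and 46.0% in rtel1-3. Bins methylated in CHG by the mean of both libraries stood at 47.6% in L119 and 51.9% in rtel1-3. Bins with a low level in either library may be among them. Gene-rich windows differed by a median of 0.0690 points, with 290 of 1007 lower, and protein-coding gene bodies had 1.17% and 1.23%. All sequence outside protein-coding genes had 23.2% and 23.0% (-0.169 points, -2.49 with coverage of at least 10, and 2.11 as a mean over cytosines with at least 4 reads in both libraries). CHH methylation of gene-poor windows was 6.62% and 6.66%. CG methylation of gene-poor windows was 69.9% and 70.9% when pooled over reads, yet 114 of 186 windows were lower with a median of -0.295 points, and pseudogenes were at 74.2% and 72.9%. Their difference became -5.18 points with coverage of at least 10 and 0.377 as a mean over cytosines covered in both libraries. Gene bodies, at 16.4% and 16.5% CG methylation, barely differed.

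**Figure D2:**
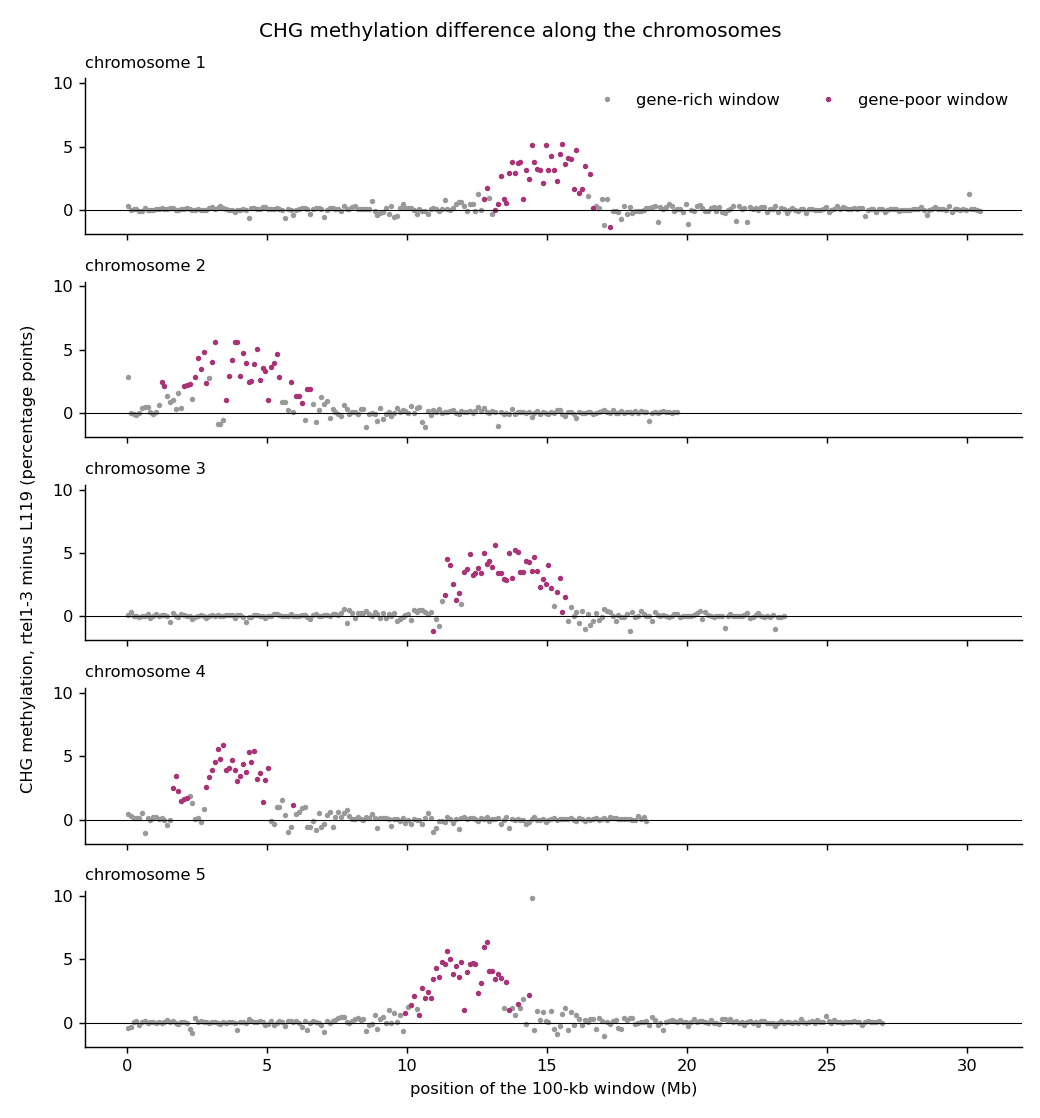
Difference in CHG methylation, rtel1-3 minus L119 (percentage points), of each 100-kb window along the 5 chromosomes (position in Mb), gene-poor windows in magenta and gene-rich windows in grey. Gene-poor windows form an arch around each centromere with a median of 3.43 points, while gene-rich windows lie near 0 with a median of 0.0690; the highest gene-rich point, on chromosome 5, rests on 508 and 327 reads.

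Over the whole nuclear genome CG methylation was 25.8% in L119 and 24.7% in rtel1-3 (-1.06 points), CHG methylation 8.15% and 8.22% (0.0658 points) and CHH methylation 2.04% and 1.98% (-0.0635 points). The CG difference was -0.796 points on chromosome 1, -1.33 on chromosome 2, -0.734 on chromosome 3, -1.36 on chromosome 4 and -1.13 on chromosome 5, and the CHG difference ranged from -0.0245 on chromosome 4 to 0.182 on chromosome 3. The 2 strands of the L119 library gave 25.8% CG methylation each, and those of rtel1-3 24.7% and 24.8%. The signs of all 3 genome-wide differences depended on how cytosines were weighted or filtered. As means over cytosines they were 0.160 points in CG (27.2% and 27.3%), 0.789 in CHG and 0.0477 in CHH. With coverage of at least 4 and 10 CHG methylation differed by -0.0354 and -0.783 points. Depth in gene-poor windows relative to L119 was lower in rtel1-3 by a median log2 ratio of -0.10, against 0.02 in gene-rich windows, so methylated repeats weigh less in its pooled levels.

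Local differences in CG methylation went both ways and lay mostly in genes. Of 464774 bins of 200 bp tested in CG, 1157 were lower in rtel1-3 and 1234 higher, with median levels of 59.0% against 2.34% in the lower bins and 10.6% against 65.1% in the higher ones. Protein-coding genes held 73.5% of the lower and 82.6% of the higher bins, against 57.7% of all tested bins. In CHG, 100 of 480728 bins were lower and 279 higher, and gene-poor windows held 46.2% of the higher bins, pseudogenes 38.4%, against 14.2% and 9.45% of tested bins. Higher CHG bins had median levels of 20.8% and 54.0%. In CHH, 416 of 583861 bins were lower and 479 higher. The same rule applied to the strands of 1 library called 46 CG bins in L119 and 54 in rtel1-3, and 64 and 44 CHG bins, where the top strand alone gave 897 CG and 183 CHG bins between the libraries. Strands show the noise within a library and set no reference for differences between plants of 1 genotype. These calls rest on Fisher's exact test of reads from 1 library per genotype, and CHG counts changed most with the read test, since 738 lower and 3726 higher bins met the minimum difference alone.

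**Figure D3:**
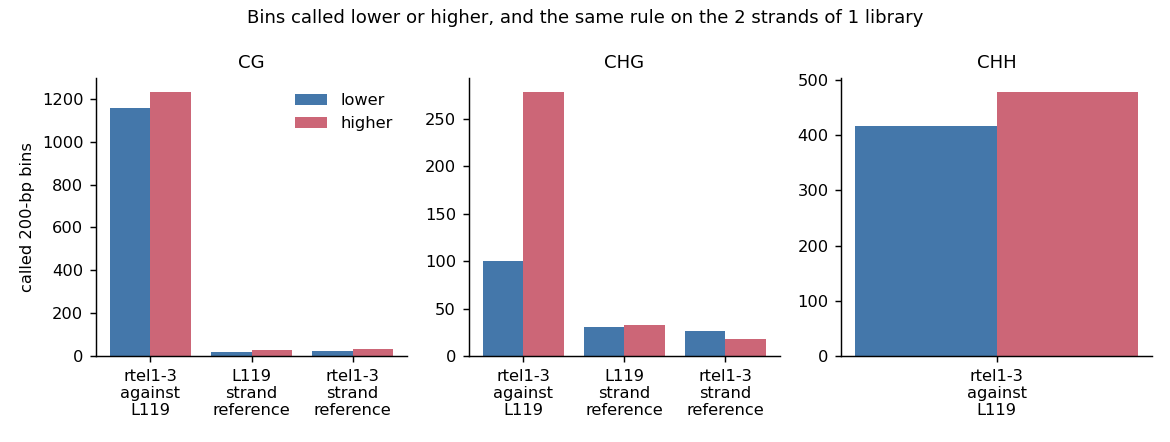
Number of 200-bp bins called lower (blue) or higher (red) in rtel1-3 than in L119, per sequence context, beside the number called between the strands of 1 library (CG and CHG only). CG calls were balanced (1157 and 1234) and CHG calls were mostly higher (100 and 279); strand comparisons, which use fewer reads and bins and show noise within a library, gave at most 33 per direction.

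Single bins went from nearly full to no methylation or the reverse. Bins within AT1G67310 (chromosome 1, 25200601 to 25200800), NOF1, a nucleolar protein gene (chromosome 1, 6085401 to 6085600), and CLC-D, a chloride channel gene (chromosome 5, 9191601 to 9191800), had CG methylation of 100%, 96.3% and 90.14% in L119 and 2.17%, 0% and 0% in rtel1-3. In the other direction, CG methylation of bins in the arginyl-tRNA synthetase gene emb1027 (chromosome 4, 13309001 to 13309200), AT5G08650 (chromosome 5, 2811601 to 2811800) and AT5G49470 (chromosome 5, 20068001 to 20068200) was 0% in L119 and 97.6%, 96.3% and 91.8% in rtel1-3. A bin 85 bp from AT4G26485 (chromosome 4, 13377401 to 13377600) had 62.4% CHG methylation in L119 and 0% in rtel1-3, and 24.9% and 0.369% CHH methylation. In AT1G75945 (chromosome 1, 28515801 to 28516000) and the pseudogene AT1G45120 (chromosome 1, 17058401 to 17058600), CHG methylation was 59.3% and 57.1% in L119 and 0% and 0.877% in rtel1-3. CHG methylation was higher in the pseudogene AT1G67626 (chromosome 1, 25343801 to 25344000; 1.02% against 62.5%), in a bin over MRD1 and the meiotic crossover gene HEI10 (chromosome 1, 19963201 to 19963400; 0% against 56.9%) and near the pseudogene AT1G36225 (chromosome 1, 13604801 to 13605000; 0.763% against 57.3%). CHH bins with the largest gains by the naming rule lay near AT2G00610, AT1G06437 and AT1G65780, at 8.94%, 14.3% and 17.3% in L119 and 34.6%, 38.5% and 39.5% in rtel1-3, and those with the largest further losses 4398 bp from AT4G08347 and near AT1G32930, at 32.6% and 36.9% against 11.7% and 16.1%. All of these 18 bins had at least 42 reads per library and passed the Fisher's exact test, the highest adjusted p being 2.59e-04.

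Loci known to be silenced by or to respond to methylation differed little or in both directions. The floral regulator FWA, whose ectopic expression follows loss of repeat methylation, had 30.9% (27.8 to 34.0) and 31.2% (28.0 to 34.5) CG methylation in its flanks and 20.3% (18.6 to 22.1) and 15.9% (14.2 to 17.7) in its body; with coverage of at least 10 the flanks had 32.9% and 29.0% and the body differed by -8.57 points. Flanks of SDC, an F-box gene silenced through tandem repeats, had 46.3% (43.5 to 49.2) and 40.4% (37.0 to 43.9), a difference that became -11.6 points with that coverage. At QQS, a starch-regulating gene under epigenetic control, body CG methylation was 23.5% (19.4 to 28.0) and 34.0% (28.8 to 39.4) and CHG methylation 18.6% (15.8 to 21.6) and 25.1% (21.6 to 28.9). The floral repressor FLC was nearly unmethylated, at 1.21% and 0.472% CG in its body. IBM1, a histone demethylase gene with a methylated intron, had 4.39% (3.93 to 4.88) and 3.55% (3.07 to 4.07) CHG methylation, and the demethylase gene ROS1 22.4% (21.2 to 23.7) and 26.1% (24.6 to 27.6) CG methylation in their bodies. None of these 6 apart from QQS was in an expression list.

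Peaks of histone H3 differed between the genotypes in number and position. The title of the series places the effect of RTEL1 on H3 in heterochromatin, and the lists held 2988 H3 peaks in L119 and 1972 in rtel1-3, covering 3.96 and 3.19 Mb. Gene-poor windows held 1879 and 1485 of them and gene-rich windows 1109 and 487. H3K9me2, the mark of constitutive heterochromatin, had 2616 and 2962 peaks over 9.01 and 8.90 Mb; H3K27me3, the Polycomb mark, 5296 and 5932 peaks over 22.1 and 20.2 Mb; and H3K4me3, the mark of active promoters, 14421 and 14146 peaks over 23.9 and 25.7 Mb. Counts have no replicate check, and above one common score minimum the order turned for H3 (906 and 986 peaks) and for H3K4me3 (4533 and 7073 peaks). H3 then had the ratio of peak numbers nearest to 1 of the 4 marks (1.09, against 1.17 for H3K9me2, 1.29 for H3K27me3 and 1.56 for H3K4me3).

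Few H3 peaks were called in both genotypes. Of the L119 H3 peaks 25.6% (24.0 to 27.2) overlapped one of rtel1-3, and of the rtel1-3 peaks 46.6% (44.4 to 48.8) overlapped one of L119. The shares were 86.8% (85.4 to 88.0) and 77.7% (76.2 to 79.2) for H3K9me2, 90.4% (89.6 to 91.2) and 89.5% (88.7 to 90.3) for H3K27me3, and 94.2% (93.9 to 94.6) and 94.7% (94.3 to 95.1) for H3K4me3. Above the common score minimum the H3K4me3 shares were 65.5% and 41.8%, and with reciprocal overlap the H3 share of rtel1-3 was 28.3%. Bases covered in both, over bases covered in either, came to 22.9% for H3, 66.7% for H3K9me2, 79.5% for H3K27me3 and 81.3% for H3K4me3. H3 peaks overlapped an H3K9me2 peak of the same genotype in 65.4% of cases in L119 and 44.4% in rtel1-3.

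**Figure D4:**
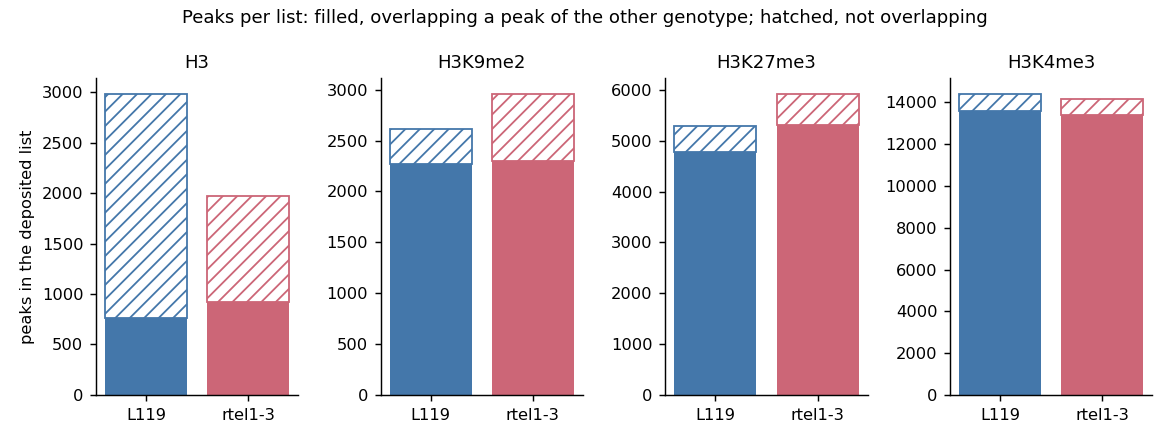
Number of peaks in the deposited list of each genotype for H3, H3K9me2, H3K27me3 and H3K4me3, filled where a peak overlaps one of the other genotype by at least 1 bp and hatched where it does not. Of H3 peaks 25.6% in L119 and 46.6% in rtel1-3 were shared, against over 77% for every other mark under this overlap rule and with all listed peaks.

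H3 peaks found in 1 genotype alone lay in different parts of heterochromatin. Those found in rtel1-3 alone fell in gene-poor windows in 78.4% of cases (826 of 1053) and those of L119 alone in 60.2% (1338 of 2224; Fisher's exact test, adjusted p = 5.22e-25), against 71.7% and 70.8% of the H3 peaks that were shared (adjusted p = 0.00176 and 9.16e-07). The first of these contrasts with shared peaks was lost with gene-poor windows defined at 40% (exact test, adjusted p = 0.455), and the second over CHG-methylated bins (adjusted p = 0.0641) and pseudogenes (adjusted p = 0.527). The first turned to -16.1 points over CHG-methylated bins and -35.0 over pseudogenes (exact test, adjusted p = 3.28e-17 and 2.10e-54). Between the genotypes, pseudogenes were overlapped by 70.4% of the L119-only H3 peaks and 31.1% of the rtel1-3-only peaks (Fisher's exact test, adjusted p = 1.62e-99), and L119 CHG-methylated bins by 85.6% and 69.9% (adjusted p = 2.77e-24). H3K9me2 peaks of 1 genotype showed the same split at pseudogenes, 53.2% in L119 and 34.4% in rtel1-3 (Fisher's exact test, adjusted p = 3.98e-08), while their shares in gene-poor windows, 58.7% and 65.2%, did not pass (adjusted p = 0.0675). The direction of a heterochromatin difference thus depended on whether gene-poor windows, pseudogenes or methylated bins defined it. These tests compare peak lists, not genotypes.

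The rtel1-3-only H3 peaks with the highest authors' scores lay in the pericentromere of chromosome 1, at 15087482 to 15092511 near AT1G40104, 15199809 to 15209440 near the pseudogene AT1G40123, and 15326920 to 15333516, 10006 bp from AT1G40143. Those of L119 lay over the pseudogenes AT5G39185 (chromosome 5, 15684893 to 15690285), AT4G07456 and AT4G07458 (chromosome 4, 4238994 to 4249877) and AT5G39155 (chromosome 5, 15671251 to 15676510). Top H3K9me2 peaks of L119 alone covered the pseudogenes AT2G06890, AT1G21020 and AT1G40071, and those of rtel1-3 alone AT1G40107, AT2G07380 and AT2G07450. All named H3K9me2 peaks of rtel1-3 alone scored 3100, and peaks of any mark tied in score were taken in order of position. FLC, the floral repressor that Polycomb silences, lay under an H3K27me3 peak listed in L119 alone (chromosome 5, 3171863 to 3181865), as did AT2G38510 and the gene SKS2. H3K27me3 peaks of rtel1-3 alone covered AT1G65481, the glutamate receptor-like gene GLR2.8 and AT3G17060. H3K4me3 peaks of L119 alone with the highest scores covered BG_PPAP, a plasmodesmal glucanase gene, AT5G19290 and RDUF2, and those of rtel1-3 alone MYB6, AT4G13575 and the light-harvesting gene LHCB6. High-scoring one-sided peaks were uneven between lists for H3 and H3K4me3, while H3K9me2 and H3K27me3 did not pass (Fisher's exact test, adjusted p = 0.117 and 0.158). For H3K9me2 and H3K27me3 the test cannot decide, because peaks tied in score entered the top 10% by their order in the list. The lowest score of that 10% was 3100 in both H3K9me2 lists and in the H3K27me3 list of rtel1-3. Of the 10% of H3 peaks with the highest score, 92 of 298 in L119 and 131 of 197 in rtel1-3 had no partner (Fisher's exact test, adjusted p = 2.07e-14). Of those of H3K4me3, 34 of 1442 in L119 and 0 of 1414 in rtel1-3 had no partner (Fisher's exact test, adjusted p = 2.01e-10), and 2 of the 61 genes beneath the 34 L119 peaks were listed as down.

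DNA damage response genes were prominent among the genes listed as up in untreated rtel1-3. In the authors' deposited table, SMR7, a cell cycle inhibitor induced by DNA damage, had a log2 fold change of 3.84, the repair gene BRCA1 1.98, GMI1, a repair factor induced by irradiation, 1.94 and the transcription factor gene NAC085 1.93. Of the 32 genes of this list, 12 were in the authors' deposited table of up genes, among them also XRI1, NAC103, PARP2, NAC044, SMR5, TSO2 and RAD17 with log2 values from 1.77 to 1.01. Within the background of genes with H3K4me3, 11 were listed against 0.588 expected (Fisher's exact test, adjusted p = 2.25e-10). Heat stress genes formed another group: 9 of 15 were in the authors' deposited table as up, 7 of the 10 in the background (Fisher's exact test, adjusted p = 2.22e-09), led by the small heat shock protein gene HSP17.6II (5.50), the heat stress transcription factor gene HSFA2 (2.87) and the chaperone genes HSP90.1 (2.11) and HSP70-4 (1.83). By the authors' own test the p of HSP17.6II was 0.00410, near the highest of its list (0.00491), against 3.16e-29 for HSP90.1. The authors' deposited table also listed the salicylic acid marker genes PR2 (1.93) and PR1 (1.51) and the jasmonate-responsive gene VSP2 (1.44) as up, 3 of 23 defence genes. All 3 lie outside the tested background. Against all protein-coding genes the adjusted p was 0.0620 over all 44 tests and 0.0362 over the 11 of untreated up genes (Fisher's exact test), so the call depends on the adjustment. None of the 29 silencing pathway, 23 cell cycle and replication, 18 histone, 22 photosynthesis, 16 flowering and 15 shoot marker genes was listed without zebularine, and of 17 root marker genes PLT2, a root stem cell factor, was listed as down by the authors' deposited table (-1.58). In the background, at most 0.588 members of any of these lists were expected among the up genes and 0.199 among the down genes. Counts of 0 therefore say little about these lists.

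The authors' untreated lists held 588 genes up and 350 down in rtel1-3. The smallest p-values among the up genes of the authors' deposited table belonged to the asparagine synthetase gene ASN1 (log2 4.65), the drought- and cold-induced gene LTI65 (2.32), the beta-xylosidase gene BXL1 (2.48), AT5G60250 (3.23) and the beta-galactosidase gene BGAL4 (2.31). Among its down genes, the authors' deposited table gave the smallest to ESM1, a glucosinolate hydrolysis modifier (-1.42), AT2G30766 (-2.35), AT3G28510 (-2.44), AT1G47395 (-1.80) and SQP1 (-1.25). QQS was listed as up by the authors' deposited table (1.70). Genes described as transposable elements made up 36 of the up and 37 of the down genes, a difference in share that did not pass (Fisher's exact test, adjusted p = 0.0754). Families with unequal shares, found by testing every description with at least 5 listed genes, were C1-domain proteins (1 up and 10 down, Fisher's exact test, adjusted p = 0.00377), UDP-glycosyltransferases (2 and 8, adjusted p = 0.0389) and pentatricopeptide repeat proteins (0 and 5, adjusted p = 0.0389). These lists rest on 2 libraries per group as the authors tested them, no values per library were analysed here, and their fold changes are taken as log2 by inference.

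With zebularine, DNA damage response and defence genes were listed as up. The authors' deposited table held 477 genes up and 234 down in rtel1-3, against a comparison group its titles do not name. It listed 10 of the 32 DNA damage response genes as up, all among the 29 in the background (Fisher's exact test, adjusted p = 5.60e-10), and the authors' deposited table gave SMR7 3.07, BRCA1 1.88 and the transcription factor gene NAC044 1.71. Of 23 defence genes 9 were listed, 4 of the 11 in the background (Fisher's exact test, adjusted p = 2.68e-04), where the authors' deposited table gave PR1 4.49, PR2 3.23, AIG1 2.60 and WRKY46 2.47. None of the 15 heat stress genes was listed, where 0.170 were expected among the up genes of the background. Of 17 root markers, 2 were listed as down in the authors' deposited table, the auxin efflux carrier gene PIN2 at -2.38 and the root hair wall protein gene PRP3 at -2.18. Both lie outside the tested background. Against all protein-coding genes the adjusted p was 0.0620 over all 44 tests and 0.0469 over the 11 of zebularine down genes (Fisher's exact test). Of 16 flowering genes, 2 were also listed as down in the authors' deposited table, FUL (-2.17) and MAF5 (-1.03), again outside the tested background. Against all protein-coding genes the adjusted p of the flowering list was likewise 0.0620 and 0.0469 (Fisher's exact test). The remaining members listed in the authors' deposited table were the light-harvesting gene LHCB1.1 (-1.09) and, up, the meristem gene STM (1.09).

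Among zebularine down genes, the smallest p-values of the authors' deposited table were tied at 5e-05, and the largest changes at that value were AT5G60530 (-3.89), DGR1 (-3.41), the chitinase-family gene AT2G43610 (-3.33), the mechanosensitive channel gene MSL9 (-3.11) and AT2G25980 (-2.94). On the up side the authors' deposited table had PR1, the receptor kinase gene CRK6 (3.73), AT5G52760 (3.42), AT1G13470 (3.36) and PR2. Families leaning to the down list were proline-rich extensin-like proteins of the cell wall (0 up and 8 down, adjusted p = 0.00262), lipid-transfer proteins (2 and 11, adjusted p = 0.00262) and peroxidases (4 and 11, adjusted p = 0.0115), by Fisher's exact test. None of the silencing pathway, cell cycle and replication and histone genes was listed. In the background, at most 0.492 members per list were expected among the up genes and 0.121 among the down genes.

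Up genes of both conditions overlapped. The up lists shared 112 genes, 9 of them DNA damage response genes, with median log2 values in the authors' deposited table of 1.51 without and 1.48 with zebularine; 55 of the 112 were larger without it. Within the background, 79 shared genes stood against 6.10 expected of independent lists (Fisher's exact test, adjusted p = 2.18e-65). Genes down without and up with zebularine numbered 21, of which 10 in the background against 2.07 expected (Fisher's exact test, adjusted p = 8.74e-05), and 13 were down in both, 3 against 0.509 (adjusted p = 0.0192); the 4 genes going from up to down included 1 in the background, against 1.501 expected. If both sets of lists used the same libraries, part of the excess may stem from that sharing. The unnamed comparison group leaves open whether the zebularine lists compare genotypes or treatments.

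H3K27me3 and H3K4me3 peaks separated up from down genes in both lines, while for H3K9me2 peaks no difference between up and down genes passed (Fisher's exact test, adjusted p = 0.319 and 0.689 in L119, 0.175 and 0.199 in rtel1-3). H3K9me2 peaks lay over at most 4 up and 5 down genes per comparison, so this test can decide little. They lay over 0.186% of untreated up genes in L119, against 2.27% of all protein-coding genes (Fisher's exact test against the other genes, adjusted p = 4.01e-04). In rtel1-3 these shares were 0% and 2.28% (exact test, adjusted p = 5.09e-05). Zebularine up genes, 0.857% in each line, did not pass (exact test, adjusted p = 0.0634). H3K27me3 peaks in L119 lay over 51.3% of the untreated down genes and 35.2% of the up genes (Fisher's exact test, adjusted p = 1.62e-05), against 29.0% of all protein-coding genes, and H3K4me3 peaks over 35.3% and 57.0% (adjusted p = 6.03e-09), against 61.4%. In rtel1-3 these shares were 47.4% and 31.8% (exact test, adjusted p = 2.01e-05) and 31.4% and 62.4% (adjusted p = 6.21e-17). With zebularine the L119 shares were 55.1% and 40.5% for H3K27me3 (Fisher's exact test, adjusted p = 5.47e-04) and 28.2% and 54.8% for H3K4me3 (adjusted p = 1.83e-10). H3 peaks of L119 lay over 8.81% of the zebularine down genes and 1.93% of the up genes (Fisher's exact test, adjusted p = 1.12e-04) and those of rtel1-3 over 6.61% and 0.428% (adjusted p = 8.29e-06). For untreated genes the shares were 2.94% and 0.745% in L119 (exact test, adjusted p = 0.0267) and 1.961% and 0.745% in rtel1-3, which did not pass (adjusted p = 0.208). H3K4me3 peaks listed in rtel1-3 alone covered 54 of 537 untreated up genes, 10.1% against 3.27% of all genes (exact test, adjusted p = 4.77e-12), and 45 of 467 zebularine up genes, 9.64% (Fisher's exact test, adjusted p = 9.64e-10), although the differences from the down genes, 4.58% untreated and 4.41% with zebularine, did not pass (adjusted p = 0.0863 and 0.131). Among the 12 up-listed DNA damage response genes, BRCA1, GMI1, SMR5 and SMR7 had such a peak and 7 had a peak in both. Peaks of L119 alone covered 26 of 306 untreated down genes, 8.50% against 3.28% (exact test, adjusted p = 1.66e-04). A difference from untreated up genes (4.66%) did not pass the exact test (adjusted p = 0.184), and such peaks were more frequent than at all genes at both zebularine up genes (27 of 467, 5.78%, adjusted p = 0.0211) and down genes (17 of 227, 7.49%, adjusted p = 0.0152). H3K27me3 peaks of L119 alone covered 36 of 537 untreated up genes, 6.70% against 3.99% of all genes (exact test, adjusted p = 0.0131), and 6.21% of the untreated down genes.

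Methylation of called genes differed by level, while the difference between the libraries mostly did not. Bodies of untreated up genes had a mean CG methylation of 4.25% in L119, and those of down genes 7.70%, 3.45 points apart with 536 and 305 genes (permutation test, p = 1e-05, the smallest it can give; adjusted p = 2.40e-04). Bodies of all protein-coding genes had a mean of 14.3%, above both lists, a difference that was not tested. Flanks of the untreated up and down genes had 8.95% and 12.6% CG (permutation test, adjusted p = 0.0146) and 2.45% and 3.72% CHG methylation (adjusted p = 0.0434), calls that ended with flanks of 500 bp (adjusted p = 0.170 for each) and, for CHG, of 2 kb (adjusted p = 0.393). Flanks of all protein-coding genes had 12.9% CG and 3.71% CHG methylation in L119. Bodies of zebularine up and down genes had 0.790% and 2.01% CHG methylation in L119 (permutation test, adjusted p = 0.0146), against 2.21% over all protein-coding genes. Of 12 tests on the rtel1-3 minus L119 difference, the CHH difference of zebularine gene bodies, 0.0414 points in up and 0.106 in down genes, was past the threshold (permutation test, adjusted p = 0.0434), and with coverage of at least 10 it was not (adjusted p = 0.172). Bins of lower CG methylation lay within 1 kb of 11 untreated up and 5 down genes, 2.05% and 1.63% (Fisher's exact test, adjusted p = 0.956), against 4.20% of all genes.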

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

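The test of RTEL1 against other gene bodies and that of base composition at the rRNA genes were chosen before their results were seen; the other tests here, and the choice of windows compared with the rRNA genes, were chosen only after.

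Bisulfite read depth over the 45S rRNA genes, which no comparison above uses, was lower in rtel1-3, with a log2 ratio to L119 of -0.32 after scaling for library size. At AT2G01010 on chromosome 2 it was -0.56 and at AT3G41768 on chromosome 3 -0.30. Over whole windows of 100 kb, those holding these genes had -0.34 and -0.34. The next window on chromosome 3, grouped with them though it holds neither gene, had -0.39. None of 1189 other windows (lowest -0.22) was as low as these 3. Base composition was argued against, since bins of the same cytosine density had a median of 0.0933, and so was a lower yield of gene-poor sequence as the whole cause, since such windows without rRNA genes had -0.10 (SD 0.06, 184 windows). A lower yield of any high-copy sequence in this library stays open, because the high-depth bins of 9 other windows, without the mitochondrial insertion of chromosome 2, had a median of -0.19 and ranged from -0.37 to 0.02, with 1 of the 9 as low. The 4 windows of that insertion went the other way, with a median of 0.20 and a range from 0.14 to 0.31. The number of rRNA gene copies was not tested.

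Within RTEL1, the 100 bp from 30075501 to 30075600 on chromosome 1 had a relative read depth in rtel1-3 of 0.145. That level was reached in 24 of 979605 bins, 16 of them in 1 stretch on chromosome 2. The bin was picked as the lowest of the gene, so its rank is not a test. CHG methylation of the gene body was 17.2% against 0.406%. Incomplete conversion at the locus was argued against, since CG methylation of the body was lower by the same reads, with a difference of -16.4 points. Reads of a further copy of the sequence were argued against by a depth of 0.893 relative to the flanks, and a gain shared by CG-methylated gene bodies by the position of RTEL1 at percentile 99.98 of such genes. What brought the CHG methylation was not tested.

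A further stretch with few reads in rtel1-3 lay on chromosome 2, from 7491886 to 7493818 between Kin3 and EXL5. Over its 1933 bp, 570 of 600 cytosines had no read in rtel1-3, and the calls numbered 31 against 7963 in L119. Whether this is a deletion carried by the line or a difference between the lines' backgrounds was not tested.

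Heat stress genes made up 9 of 588 genes listed as up without zebularine and 0 of 477 with it (Fisher's exact test, p = 0.00533, adjusted over 8 tests 0.0427); this test of the difference was added after the counts were seen and compares lists, not conditions. The zebularine lists name no comparison group and were made differently, and the cause of the difference was not tested.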

How the results depend on the processing

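The means over cytosines covered in both libraries, pseudogenes as the definition of heterochromatin, flanks of 500 bp or 2 kb, other regions around called genes for the marks, expression lists limited to the gene table or to a log2 fold change under 5, and coverage of at least 10 at named loci were chosen after seeing the data. Of 403 alternative values, 216 kept direction and call or stayed within their interval, 122 moved, 8 lost and 2 gained a call, and 55 changed direction, 27 of them between values that both missed the threshold, and except where a construction is named the cause was not tested. Of 48 values on marks at called genes 46 were kept, of 11 on gene lists 5 and of 42 at named loci 37. With coverage of at least 10, the 5 others differed by -18.6 points in RTEL1 body CG, -11.6 and 2.48 in SDC flank CG and CHG, and -8.57 and -0.597 in FWA body CG and CHH. No paired analysis was possible because the deposited expression tables hold no values per replicate, and for the same reason no RNA replicate was left out and no expression filter was applied. Conversion from chloroplast reads, organellar peaks, transposon superfamilies and strand-specific flanks were not run, since the tables used hold none of these.

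The genome-wide CG difference was -1.23 points with coverage of at least 4, -2.46 with at least 10, 0.160 as a mean of per-cytosine levels, 0.270 as that mean over cytosines covered in both libraries, -1.11 and -1.01 on the top and bottom strand, and -1.13 to -1.001 with 1 chromosome left out. For CHG these were -0.0354, -0.783, 0.789, 0.782, 0.0416, 0.0900 and 0.0401 to 0.0924, and for CHH -0.0803, -0.198, 0.0477, 0.0612 and, with a chromosome left out, -0.0709 to -0.0586. A coverage minimum of 10 keeps fewer cytosines of the shallower rtel1-3 library by construction, and depth limits these levels.

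In gene-poor windows the CG difference was 0.715 with coverage of at least 4, -1.43 with at least 10, 0.354 as a mean over cytosines covered in both, and 1.65 and -0.219 with gene-poor windows defined at 15% and 40%. For CHG these were 3.28, 1.68, 4.03, 4.02 and 2.15, and for CHH 0.0210, -0.157, 0.144, 0.102 and -0.0505. Pseudogenes had CG differences of -1.65, -5.18 and 0.377 and CHG differences of 2.88, 1.14 and 4.01 under coverage of 4, of 10 and the mean. Gene bodies had -0.146 and 0.343 in CG, and CHG-methylated bins 3.78 and 4.40 in CHG, under coverage of 10 and the mean. CHG methylation was higher under every one of these alternatives.

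Called CG bins numbered 2474 lower and 2783 higher with the smaller minimum difference, 482 and 502 with the larger, 2423 and 2760 in bins of 100 bp, 147 and 109 in bins of 500 bp, 661 and 718 with coverage of 10, and 448 and 449 or 459 and 544 on the top or bottom strand. CHG bins numbered 738 and 3726 on the difference alone, 59 and 102 with the larger minimum, 58 and 157 with coverage of 10, 48 and 135 or 45 and 108 on single strands, and 54 lower ones in bins of 500 bp. CHH bins numbered 1482 and 1646 on the difference alone, 153 and 154 with the larger minimum, 105 and 70 in bins of 500 bp, and 140 and 175 with coverage of 10.

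Above a common score minimum, rtel1-3 had 80 more H3 peaks and 0.162 Mb more, 211 more H3K9me2 peaks and -0.353 Mb, 0.00010 Mb more H3K27me3, and 2540 more H3K4me3 peaks and 4.73 Mb more. Scores are set within a list, which this minimum ignores. With peaks closer than 500 bp merged, the differences were 185 for H3K9me2 and 311 for H3K27me3, and in the upper 75% by score covered length differed by -0.396 Mb for H3K9me2 and 0.912 Mb for H3K4me3.

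Shared H3 peaks made up 18.8% of L119 when overlap had to cover 50% of the peak, 18.7% and 28.3% of L119 and rtel1-3 with reciprocal overlap, 29.8% and 50.1% within 500 bp and 29.7% and 31.1% above the common minimum. For H3K9me2 the last 3 were 80.3% and 70.9%, 89.3% and 81.8%, and 81.4% and 71.2%, with 75.6% of rtel1-3 under 50% overlap; for H3K27me3 86.6% and 77.3%, 91.5% and 91.1%, and 84.5% and 70.4%, with 87.0% of L119 under 50% overlap. For H3K4me3 they were 91.6% and 93.4%, 94.9% and 95.3%, and 65.5% and 41.8%, with 93.7% of rtel1-3 under 50% overlap.

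Heterochromatic share, 1-genotype minus shared peaks, was for H3 in L119 -3.13 points over CHG-methylated bins (exact test, adjusted p = 0.0641) and -1.44 over pseudogenes (adjusted p = 0.527), and for H3 in rtel1-3 1.48 with gene-poor at 40% (adjusted p = 0.455), -16.1 over methylated bins (adjusted p = 3.28e-17) and -35.0 over pseudogenes (adjusted p = 2.10e-54). H3K9me2 had in L119 9.85 with reciprocal overlap and -12.6 over pseudogenes, and in rtel1-3 -10.7 over methylated bins and -32.2 over pseudogenes; H3K27me3 of L119 had -7.71 over methylated bins and H3K4me3 of rtel1-3 2.75 with gene-poor at 40%. Between the genotypes, rtel1-3 minus L119 was -15.7 and -39.3 for H3 over methylated bins and pseudogenes, and for H3K9me2 1.67 with reciprocal overlap, -9.44 over methylated bins and -18.8 over pseudogenes.

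With an absolute log2 fold change of at least 1.5 or 2, the authors' deposited tables kept 278 or 124 untreated up genes, 161 or 112 down, 213 or 98 zebularine up and 103 or 53 down. At 2 in both, the overlaps of untreated down genes with zebularine up and down genes held 0 genes of the tested background, an observed over expected of 0 each, since fewer genes were compared, and 4 and 0 genes in all. For called genes, the up minus down CHH difference of zebularine bodies was -0.0480 with coverage of 10 (permutation test, adjusted p = 0.172), flank CG levels differed by -2.39 with flanks of 500 bp (adjusted p = 0.170), and flank CHG levels by -1.09 with 500 bp (adjusted p = 0.170) and -0.738 with 2 kb (adjusted p = 0.393).

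The values that changed direction without passing a test under either choice were these. Heterochromatic share, 1-genotype minus shared peaks, was in L119 -1.57 within 500 bp and -0.830 over methylated bins for H3K9me2, -2.43 with gene-poor at 40%, -0.0813 with reciprocal overlap and -2.89 over pseudogenes for H3K27me3, and for H3K4me3 -0.0911 and -1.27 with gene-poor at 15% and 40%, -0.516 with reciprocal overlap, -1.54 over methylated bins and -0.288 over pseudogenes. For H3K27me3 in rtel1-3 it was -0.217 with reciprocal overlap, -1.88 over methylated bins and -1.45 over pseudogenes. H3K9me2 of L119 at zebularine genes, up minus down, was 0.379 with 500 bp to each side and 0.165 with 1 kb around either end. Among called genes, the up minus down difference with coverage of 10 was 0.0120 for untreated body CHG, -0.177 for zebularine flank CG, 0.0205 for untreated flank CHG and -0.0113 for zebularine flank CHH, and with flanks of 500 bp 0.137 and -0.0070 for the last 2. Against all protein-coding genes, which brings listed members into the background, observed over expected went from 0 to 8.52 for silenced loci and 6.67 for defence (untreated up), 5.28 for root markers (untreated down), 15.1 and 14.2 for flowering and root markers (zebularine down) and 3.92 for shoot markers (zebularine up).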

Other observations

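The tests on CHG-methylated bins other than that of depth, and all gene lists and genes of the following paragraph, were chosen only after the results were seen.

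Lists drawn up from genes already seen as called cannot be tested on the same calls, so counts alone are given. Of a list of 15 iron deficiency genes, 6 were in the authors' down list without zebularine and 9 in their up list with it. The comparison group of the latter is not named, so that an opposite direction stays open. In the authors' deposited table the regulator bHLH38 had log2 values of -2.56 and 2.27 and the iron signalling peptide gene IMA1 -2.06 and 2.23. Genes induced by darkness and sugar starvation were listed as up without zebularine, 7 of 8, with ASN1 at 4.65 and SEN1 at 3.37 in the authors' deposited table, and 2 of 8 with it, ASN1 at 1.45 and DIN10 at 1.06. Shade genes followed, 5 of 8 untreated, with PIF4 at 1.82, PIF5 at 1.31 and HB2 at 2.40 in the authors' deposited table, and 0 with zebularine. OFP14, the neighbour of RTEL1, was down at -1.13 in the authors' deposited table and had bins of lower CG and higher CHG methylation within 1 kb. That window was not separated from RTEL1, whose own body held such changes, so the bins may lie in RTEL1.

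Bins with CHG methylation by the mean of both libraries had 47.6% in L119 and 51.9% in rtel1-3. They were not chosen by L119 alone, so bins with a low level in L119 may be among them. Incomplete conversion in the rtel1-3 library was argued against, since CHG methylation of all other bins differed by 0.0622 points, and so was its lower depth, since cytosines with equal reads in both libraries differed by 4.27 points. Preferential recovery of methylated molecules was argued against by the odds ratio of CHH methylation in the same bins, 1.02 against 1.19 for CHG. More CHG methylation of heterochromatin in rtel1-3 may thus be biological, as a hypothesis from 1 library per genotype; a difference between seedling batches was not tested.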
